A study of Mus musculus with 8 samples.

How the data were processed

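RNA from the livers of male C57BL/6J mice, an inbred laboratory strain, was measured by bulk RNA sequencing in 8 libraries. Per the labels, 4 libraries belong to a group named NASH (nonalcoholic steatohepatitis, a fatty liver with inflammation) and 4 to a group named WT, with replicate numbers 1 to 4 in each. Every sample carries the wild-type genotype, so WT is used here as a group name and not as a contrast to a mutant. The design text describes mice obtained at 8 weeks of age that ate a normal diet or a diet rich in fat, cholesterol and fructose for 28 weeks. Reading NASH as the rich diet and WT as the normal diet is an interpretation made here, since the labels do not tie the group names to the diets. The labels number the replicates but do not state that each library came from its own animal, so the p-values measure the spread between these libraries, which may be partly technical.

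Per the labels' protocols, frozen liver was extracted with Trizol and the libraries were made with a TruSeq stranded total RNA kit. HISAT2, an aligner, and HTSeq 0.9.1, which assigns reads to genes, are named in the submitters' processing notes. The same notes list the mouse builds mm9 and mm10 without saying which was used for what. The strand setting of the counting and the annotation are not given in the sources used here. The deposited table holds raw read counts per gene, per the file headers, for 16122 genes, all of them protein coding and each with at least 1 read. The authors' normalized values fill 8 further columns of the same table, and these were not used. A count takes no account of gene length, so levels are compared between libraries for the same gene and not between genes. Reads that near-identical genes share can be split between them or lost, so values of Mup13, Saa1, Saa2, Cyp2c54, Cyp4a10, Cyp2b10, Gstm3, Serpina1a, Serpina1e, Hsd3b5 and Acot1, which belong to families of close paralogs, are less certain than others.

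The counts per library summed to between 25760117 and 32684719. Scaling used edgeR's trimmed mean of M-values (TMM), and genes were kept by edgeR's filter for low counts with its default settings, which left 12351 genes. The 2 groups were compared with edgeR's quasi-likelihood F-test (version 4.0.16, robust estimation, R 4.3.3) on all 8 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All adjusted p-values of single genes are from this edgeR test unless another tool is named, and all tests were two-sided. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM (counts scaled to a common library total) after TMM scaling, as mean ± SD over the 4 libraries of a group. The biological coefficient of variation was 29.2%. Where a gene had no count in a group, the fold was computed against a floor of 3 counts over that group, which covers counting error only.

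On simulated data with the same library sizes and means, tested over 12218 genes for NASH against WT, the test recovered 6% of the genes changed 1.5-fold, 36% of those changed 2-fold, 74% of those changed 4-fold and 94% of those changed 8-fold. Of its 120 calls, 7 were unchanged genes (5.83%). Changes of 2-fold or less were thus often missed in the simulation. It changed 50 genes at each fold, while 2338 genes passed in the real data. The simulation also raised a separate small gene list 2-fold, whose calls count among the 120 but not in the shares recovered. Fewer true changes make the adjusted threshold stricter, and both simulated groups had the same spread. The shares recovered may therefore differ in the real data.

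Before the data were examined, the design, the gene lists, the rule for naming genes and the alternative settings were fixed. The lists hold 672 entries in 34 groups, 14 chosen for the disease and the diet and 20 for cell types and processes that could shift in liver. In the table, 643 entries were found, and 7 genes stand in more than 1 list. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation between genes of 0.01. Each was tested again with the correlation estimated from the data, and with fry, a rotation test that asks whether a list's own genes move on balance in 1 direction and makes no comparison with other genes. For each list the members passing are given over all genes tested and adjusted over the list alone. A list score is the mean log2 CPM of the tested members in a library less their mean over the 8 libraries. Bootstrap intervals were made by resampling the genes of a list, not the libraries. They leave out the spread between libraries and treat genes that move together as independent, so they are likely too narrow.

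The genes named by rule are the 5 with the largest log2 fold change in each direction, the 2 members of each disease list and the 1 member of each called context list with the smallest adjusted p, 13 anchor genes of the disease and diet, and Y-linked genes as a check of the sex given in the labels. The 5 in each direction had to pass the threshold and reach a mean CPM of 1 over all 8 libraries. They also had to have every NASH library on the same side of every WT library and carry no predicted or clone-based symbol. This gave 60 genes, of which 59 were tested, and some results of single genes are not reported here. Other genes named as examples of a list were chosen after their values were seen, mostly among those that stayed past the threshold with each library left out in turn.

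Gene positions are those of GENCODE M21 on GRCm38 by gene identifier, 1-based. Of the 16122 identifiers, 15981 are in that annotation, and the table itself gives no coordinates. Exons of 7 of the 60 named genes overlap exons of a gene on the opposite strand (Slc13a2, Srebf1, Irs1, Rtn4, Mmp12, Cx3cr1 and Ccnd1), whose reads cannot be told apart if the strand was ignored in counting. Exons of 4 overlap a gene on the same strand (Srebf1, Scd2, Spp1 and Top2a).

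Libraries were described by principal components of log2 CPM (prior count 2) of the 500 most variable tested genes and by Spearman correlations across genes. Within the groups, the counts of any pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 20.5 to 453), so no pair looked like the same library sequenced again. Libraries made separately from the same liver may also differ by more than sampling noise. All were kept as separate replicates, but this comparison does not show that they came from separate animals. The alternatives tried were DESeq2-type size factors, library totals alone, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of 1 CPM in every library of a group, a test against a fold change of 1.5, the replicate number as a block and leaving out each library in turn. KEGG pathways from the deposited annotation with 10 to 300 tested genes, and fry in each regrouping of the libraries, were added after the data had been seen, as were the list medians with library totals alone, the sum of the sex-biased medians under both scalings, camera on the pathways in each regrouping, that sum without members of the macrophage list, the bound for Slc7a11 with single libraries left out and the 5 library measures compared between groups by exact permutation tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.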

Results

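Liver RNA of 4 NASH and 4 WT libraries was counted to find which genes differ between the livers of these groups. The counts summed to 26270597, 25760117, 28274613 and 26270596 in NASH replicates 1 to 4 and to 27204662, 30461386, 32684719 and 32603193 in WT replicates 1 to 4. In NASH livers 15 of 16 macrophage, 30 of 35 extracellular matrix, 17 of 26 interferon and 12 of 24 cell cycle genes tested were higher, and 9 of 22 male-biased and 7 of 17 circadian clock genes were lower. None of these lists passed camera with an estimated correlation (adjusted p = 0.251 to 0.312). Of the 12351 genes tested, 1597 were higher and 741 lower in NASH (edgeR, adjusted p under 0.05), and 10013 did not pass. Among the genes that passed, 1165 were more than 2-fold higher and 158 more than 2-fold lower. The libraries of the 2 groups did not overlap for 3305 of the 12351 genes tested, where chance would separate 2.86% of genes. With library totals alone in place of TMM, 3071 genes were higher and 220 lower, so that 93.3% of the calls were higher against 68.3% with TMM. That scaling raised the median log2 fold change of all genes by 0.36, and 1801 genes were called under both.

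The number of genes passing rested on the libraries included. It was 3742 without NASH replicate 1, 1114 without NASH replicate 4, and 821, 1298, 1085 and 1292 without WT replicates 1, 2, 3 and 4. Of the 2338 genes, 744 passed with each of the 8 libraries left out in turn, as did 97 of the 196 that belong to a gene list and 37 of the 51 named by rule that passed.

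The libraries separated by group along the first principal component, which held 74.7% of the variance of the 500 most variable genes. WT libraries lay between −34.6 and −25.6 on it. NASH replicates 1 to 4 lay at 5.10, 19.3, 54.5 and 44.5, so the NASH libraries were spread over a wider range than the WT libraries. The second component held 7.21% and set WT replicate 4 apart from the other WT libraries, at −19.1 against 0.152 to 3.44. Spearman correlations across genes, which are not independent replicates, were 0.928 to 0.984 between NASH libraries, 0.983 to 0.993 between WT libraries and 0.888 to 0.977 between groups. Alb, the gene of serum albumin made by hepatocytes, took 7.24% ± 2.01 of the counts in NASH and 11.6% ± 1.40 in WT (SD, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 allows, 0.0571 adjusted over 5 library measures). The 5 mitochondrially encoded genes in the table took 1.39% ± 0.492 of the counts in NASH and 2.09% ± 0.174 in WT (exact permutation p = 0.0571, also 0.0571 adjusted).

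**Figure D1:**
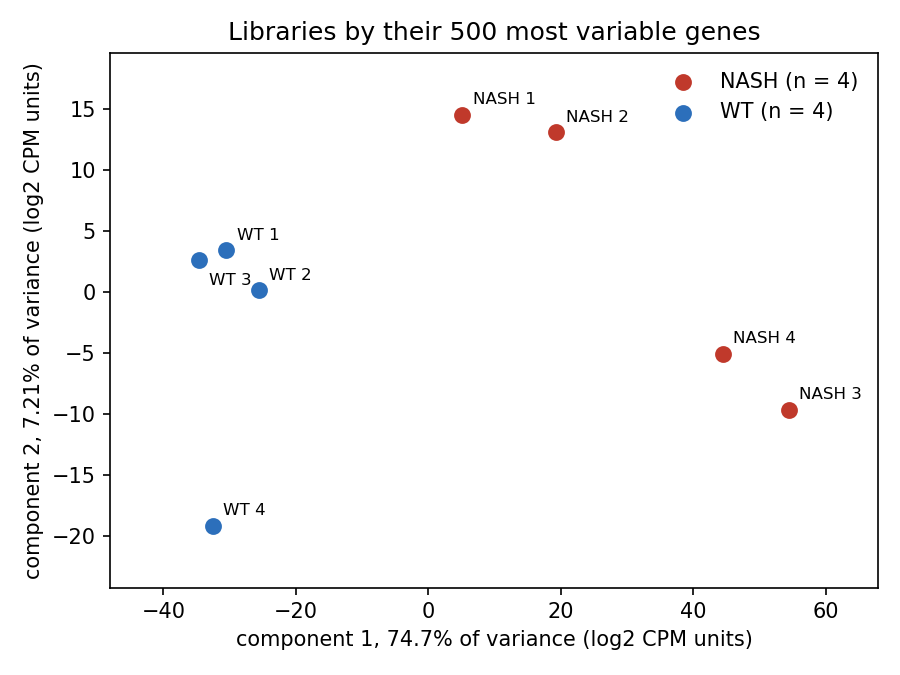
Each point is 1 library placed by the first 2 principal components of log2 CPM of the 500 most variable tested genes (axes in log2 CPM units), coloured by group, 4 libraries each. The NASH libraries lie from 5.10 to 54.5 on component 1, all above the WT libraries, which lie from −34.6 to −25.6.

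The largest rises included genes of lipid-handling macrophages. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a transmembrane glycoprotein of phagocytes, reached 259 ± 226 CPM in NASH against 2.21 ± 0.908 in WT (SD, n = 4 each, log2 fold change 6.87 ± 0.81 SE, adjusted p = 0.00343). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor of macrophages, stood at 17.6 ± 12.8 against 0.173 ± 0.156 CPM (log2 fold change 6.69 ± 0.78, adjusted p = 0.00343). Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine transporter subunit xCT, had 403 counts in NASH and 0 in WT, which makes it at least 120-fold higher against a floor of 3 counts over the WT group (adjusted p = 0.0168). NASH replicate 3 held 288 of the counts, and without it the bound was 50.6-fold. Sdcbp2 (ENSMUSG00000027456, chromosome 2, 151572622 to 151590005) rose by 6.38 ± 0.84 on the log2 scale and Gdf3 (ENSMUSG00000030117, chromosome 6, 122605403 to 122610087), a growth factor of the TGF-beta superfamily, by 6.31 ± 0.83 (adjusted p = 0.0042 for both). Single libraries moved these log2 fold changes, to 6.23 for Gpnmb without NASH replicate 3, to 7.33 for Trem2 and 7.31 for Sdcbp2 without WT replicate 1, and to 7.57 for Gdf3 without WT replicate 3. The WT group held 10 counts of Sdcbp2 and 4 of Gdf3 in all, against 1093 and 428 in NASH, so the size of both rises is uncertain.

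The largest falls were led by Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), a male-biased steroid-metabolising enzyme, at 1.24 ± 0.528 CPM in NASH against 66.1 ± 25.1 in WT (SD, n = 4 each, log2 fold change −5.77 ± 0.42 SE, adjusted p = 0.000827). Gpr110 (ENSMUSG00000041293, chromosome 17, 43270329 to 43324737), an adhesion-type receptor, fell by 4.40 ± 0.63 (adjusted p = 0.00588) and the dicarboxylate transporter Slc13a2 (ENSMUSG00000001095, chromosome 11, 78397087 to 78422217) by 4.10 ± 0.73 (adjusted p = 0.00983). The chemokine Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) fell by 5.01 ± 1.15 (adjusted p = 0.0193), but not past the threshold without NASH replicate 4 (0.0514), WT replicate 1 (0.0533) or WT replicate 2 (0.0521), nor with limma-voom (0.479). Mup13 (ENSMUSG00000089873, chromosome 4, 61224307 to 61228286), a major urinary protein with near-identical paralogs, fell by 4.15 ± 1.07 (adjusted p = 0.0282). Its call was lost without NASH replicate 2 (0.0591) or 4 (0.0525) and without WT replicate 1 (0.0648), 3 (0.0572) or 4 (0.0669). Limma-voom did not call Gpr110 (adjusted p = 0.0574). The log2 fold change of Cxcl13 was −4.06 without WT replicate 2, and that of Mup13 was −5.56 without NASH replicate 1.

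**Figure D2:**
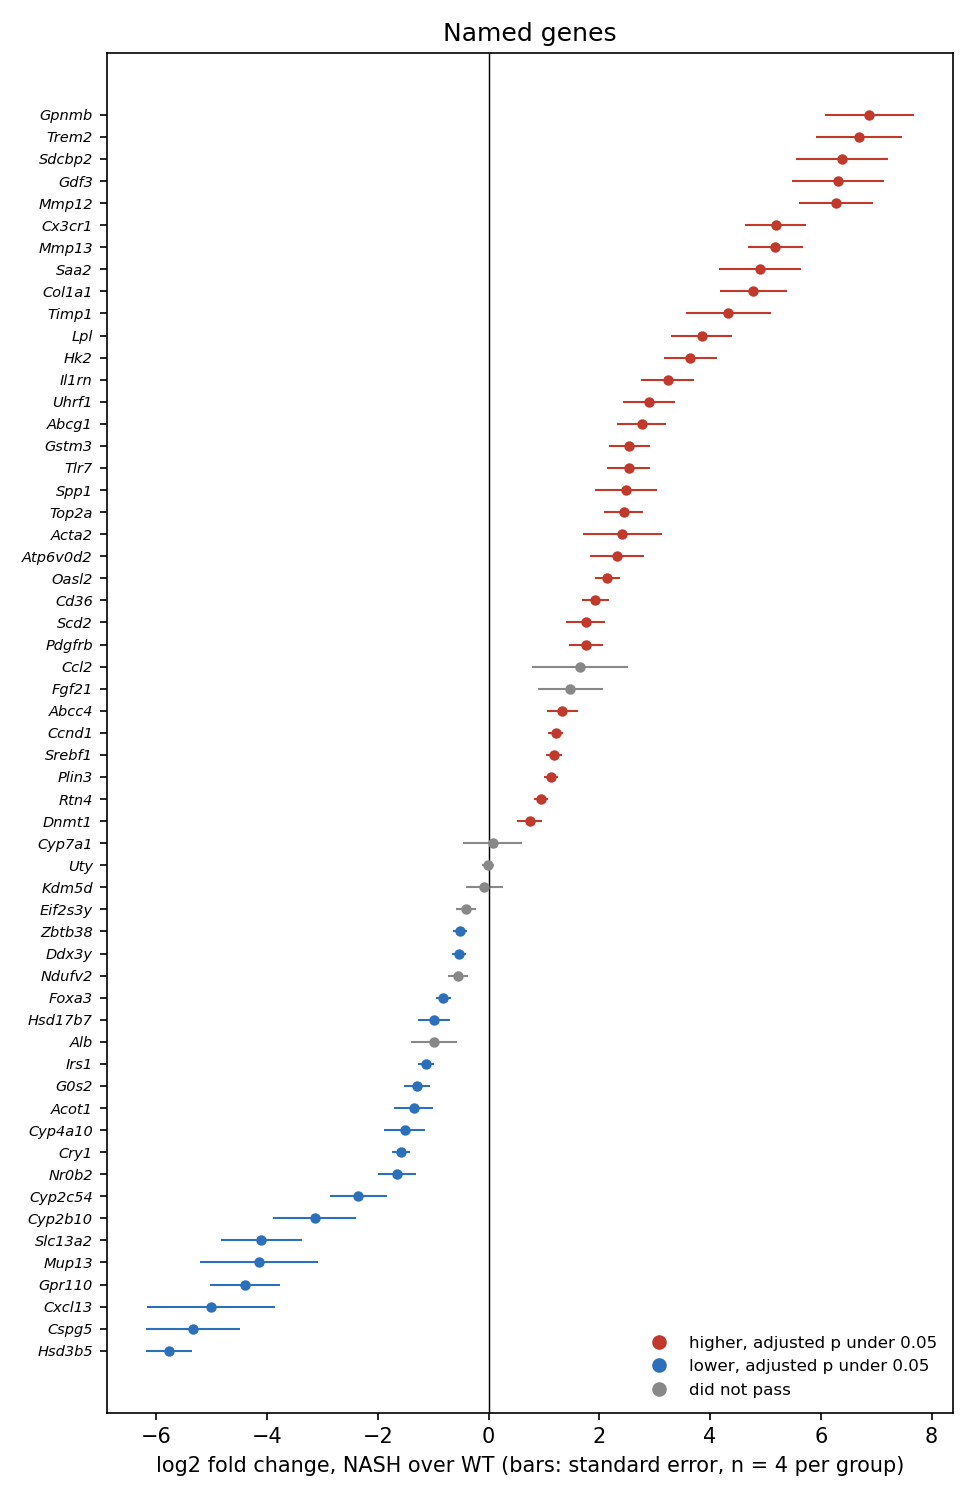
Log2 fold change of NASH over WT for the tested genes named by rule that are reported here, with bars for the standard error (n = 4 libraries per group) and colours for whether a gene passed. Slc7a11 is left out because WT held no count of it, and values run from 6.87 for Gpnmb to −5.77 for Hsd3b5.

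Markers of lipid-associated and monocyte-derived macrophages rose almost as a block. Of the 16 tested members, 15 were higher in NASH, and the other, the lipid-binding protein gene Fabp5, did not pass (log2 fold change 0.74 ± 0.51, adjusted p = 0.314). The median log2 fold change was 3.41. Mmp12 (ENSMUSG00000049723), an elastase of macrophages, rose by 6.27 ± 0.67 and the fractalkine receptor Cx3cr1 (ENSMUSG00000052336) by 5.18 ± 0.55 (adjusted p = 0.00271 for both), with further rises in the monocyte chemokine receptor Ccr2 (3.86 ± 0.50), Itgax (4.11 ± 0.58) and Lgals3 (4.48 ± 0.65). Without NASH replicate 3 the log2 fold changes of Mmp12 and Itgax were 5.38 and 3.33. The vacuolar proton pump subunit Atp6v0d2 rose by 2.32 ± 0.49 (adjusted p = 0.0152) and lost the call without WT replicate 1 (0.0505). Camera called the list (adjusted p = 2.8e-17), while adjusted p = 0.251 with an estimated correlation, and fry gave 0.0212. The count adjusted over the list alone was also 15 higher, and 12 of the 15 passed with each library left out in turn. Scores of the list were 0.58 and 1.01 in NASH replicates 1 and 2 and 2.96 and 2.20 in replicates 3 and 4, against −2.01 to −1.53 in WT.

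Inflammatory cytokines, chemokines and sensors rose in 11 of 21 tested members (16 adjusted over the list alone), and 10 did not pass. The interleukin-1 antagonist Il1rn (ENSMUSG00000026981) rose by 3.23 ± 0.49 (adjusted p = 0.00651) and the RNA sensor Tlr7 (ENSMUSG00000044583) by 2.53 ± 0.38 (adjusted p = 0.00664), and the chemokines Ccl3 and Ccl5 rose by 4.44 ± 0.81 and 2.64 ± 0.47. The log2 fold change was 2.61 for Il1rn without NASH replicate 3 and 5.86 for Ccl3 without WT replicate 2. Ccl2, a chemokine that draws monocytes, stood at 5.48 ± 6.77 CPM in NASH and 1.76 ± 1.27 in WT, a log2 fold change of 1.66 ± 0.87 that did not pass (adjusted p = 0.199). Tnf lay below the filter at 0.791 ± 0.893 and 0.165 ± 0.145 CPM and was not tested. The median log2 fold change of the list was 1.76 (camera adjusted p = 8.4e-08, adjusted p = 0.312 with an estimated correlation, fry 0.0228). Of the 11 calls, 5 held with each library left out.

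Extracellular matrix and fibrosis genes were higher in 30 of 35 tested members (33 adjusted over the list alone), and the other 5 did not pass. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the main chain of type I collagen, stood at 100 ± 78.4 CPM in NASH against 3.64 ± 1.22 in WT (SD, n = 4 each, log2 fold change 4.78 ± 0.60 SE, adjusted p = 0.00379). The collagenase Mmp13 (ENSMUSG00000050578) rose by 5.17 ± 0.50 (adjusted p = 0.00199), the protease inhibitor Timp1 (ENSMUSG00000001131) by 4.33 ± 0.76 (adjusted p = 0.0094), Col3a1 by 3.81 ± 0.46 and the small proteoglycan gene Lum by 2.76 ± 0.44. The log2 fold change of Col1a1 was 4.10 without NASH replicate 4 and that of Timp1 was 5.88 without WT replicate 4. Of the 9 counts of Timp1 in WT, 7 were in WT replicate 4, so the size of its rise is uncertain. The list had a median log2 fold change of 2.03 (camera adjusted p = 1.7e-24, adjusted p = 0.251 with an estimated correlation, fry 0.0164). With each library left out, 18 of the 30 calls held. Its score was 0.09 in NASH replicate 1 and 1.07, 1.42 and 1.74 in the others, against −1.16 to −1.02 in WT.

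Stellate cell and fibroblast markers, which mark the matrix-producing cells of the liver, rose in 7 of 15 tested members (10 adjusted over the list alone). The growth factor receptor Pdgfrb (ENSMUSG00000024620) rose by 1.76 ± 0.31 (adjusted p = 0.00978) and Vim by 2.32 ± 0.44, and these 2 calls held with each library left out. The smooth muscle actin gene Acta2 (ENSMUSG00000035783) rose by 2.41 ± 0.71 (adjusted p = 0.0431). Its call was lost without NASH replicate 3 (0.0796) or 4 (0.105), without WT replicates 1 to 4 (0.0994, 0.104, 0.101 and 0.0851), with limma-voom (0.0868) and without the low-count filter (0.0673), and its log2 fold change was 1.33 without NASH replicate 4. The median of the list was 0.93 (camera adjusted p = 0.00057, adjusted p = 0.463 with an estimated correlation, fry 0.0524).

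Interferon-induced genes were higher in NASH in 17 of 26 tested members (21 adjusted over the list alone), and all 26 had a positive log2 fold change. Oasl2 (ENSMUSG00000029561), an antiviral protein of the oligoadenylate synthetase family, rose by 2.15 ± 0.22 (adjusted p = 0.00241), Oas1a by 2.33 ± 0.30, Usp18 by 2.32 ± 0.45 and Ifi44 by 2.20 ± 0.29. The median was 1.13 (camera adjusted p = 1.6e-14, adjusted p = 0.251 with an estimated correlation, fry 0.0060). Of the 17 calls, 13 held with each library left out. The list's score was lowest among NASH libraries in replicate 3, at 0.11 against 0.62 to 0.81 in the others and −0.64 to −0.45 in WT.

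Cell cycle genes rose in 12 of 24 tested members, and the ribonucleotide reductase subunit Rrm2 fell (18 and 1 adjusted over the list alone). Top2a (ENSMUSG00000020914), the topoisomerase of dividing cells, rose by 2.44 ± 0.36 (adjusted p = 0.00588), the proliferation marker Mki67 by 2.59 ± 0.39 and the mitotic regulator Foxm1 by 3.32 ± 0.52. Rrm2 fell by 0.70 ± 0.21 (adjusted p = 0.0474), but not with library totals alone (0.192) or without NASH replicates 1, 3 or 4 (0.0515, 0.0743 and 0.0904) or WT replicates 1, 2 or 4 (0.117, 0.119 and 0.0966). The list's median was 1.55 (camera adjusted p = 4.9e-08, adjusted p = 0.312 with an estimated correlation, fry 0.0212). Of its 13 calls, 6 held with each library left out. The score was −0.04 in NASH replicate 1 and 0.76 to 1.40 in the others, against −1.14 to −0.69 in WT.

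Liver tumour and oncofetal genes rose in 5 of 10 tested members (7 adjusted over the list alone), among them the cyclin Ccnd1 (ENSMUSG00000070348, 1.21 ± 0.13, adjusted p = 0.00271) and the cell surface protein gene Ly6d (5.24 ± 0.72), whose calls held with each library left out, with Ly6d at 4.64 without NASH replicate 3. The median was 1.91 (camera adjusted p = 0.00034, adjusted p = 0.312 with an estimated correlation, fry 0.0212). NRF2 targets, which serve antioxidant defence, rose in 7 of 16 (8 adjusted over the list alone). The glutathione transferases Gstm3 (ENSMUSG00000004038) and Gsta1 rose by 2.54 ± 0.37 (adjusted p = 0.00588) and 2.55 ± 0.50. The list's median was 0.68, unchanged with Slc7a11 at its lower bound, and 1.08 with library totals alone (camera adjusted p = 0.0072, adjusted p = 0.251 with an estimated correlation, fry 0.0060). Of the 7 calls, 3 held with each library left out. Acute phase proteins, secreted by hepatocytes in inflammation, rose in 9 of 22, and adjusted over the list alone 14 were higher and 1 lower. Serum amyloid Saa2 (ENSMUSG00000057465) rose by 4.90 ± 0.74 (adjusted p = 0.00651), the iron-chelator carrier Lcn2 by 5.96 ± 1.10 and Orm2 by 4.67 ± 0.87. The log2 fold changes of Saa2 and Lcn2 were 4.24 and 5.19 without NASH replicate 3, and that of Orm2 was 4.05 without NASH replicate 4. That list had a median of 0.97 (camera adjusted p = 0.00025, adjusted p = 0.578 with an estimated correlation, fry 0.1). Of the 9 calls, 4 held with each library left out.

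**Figure D3:**
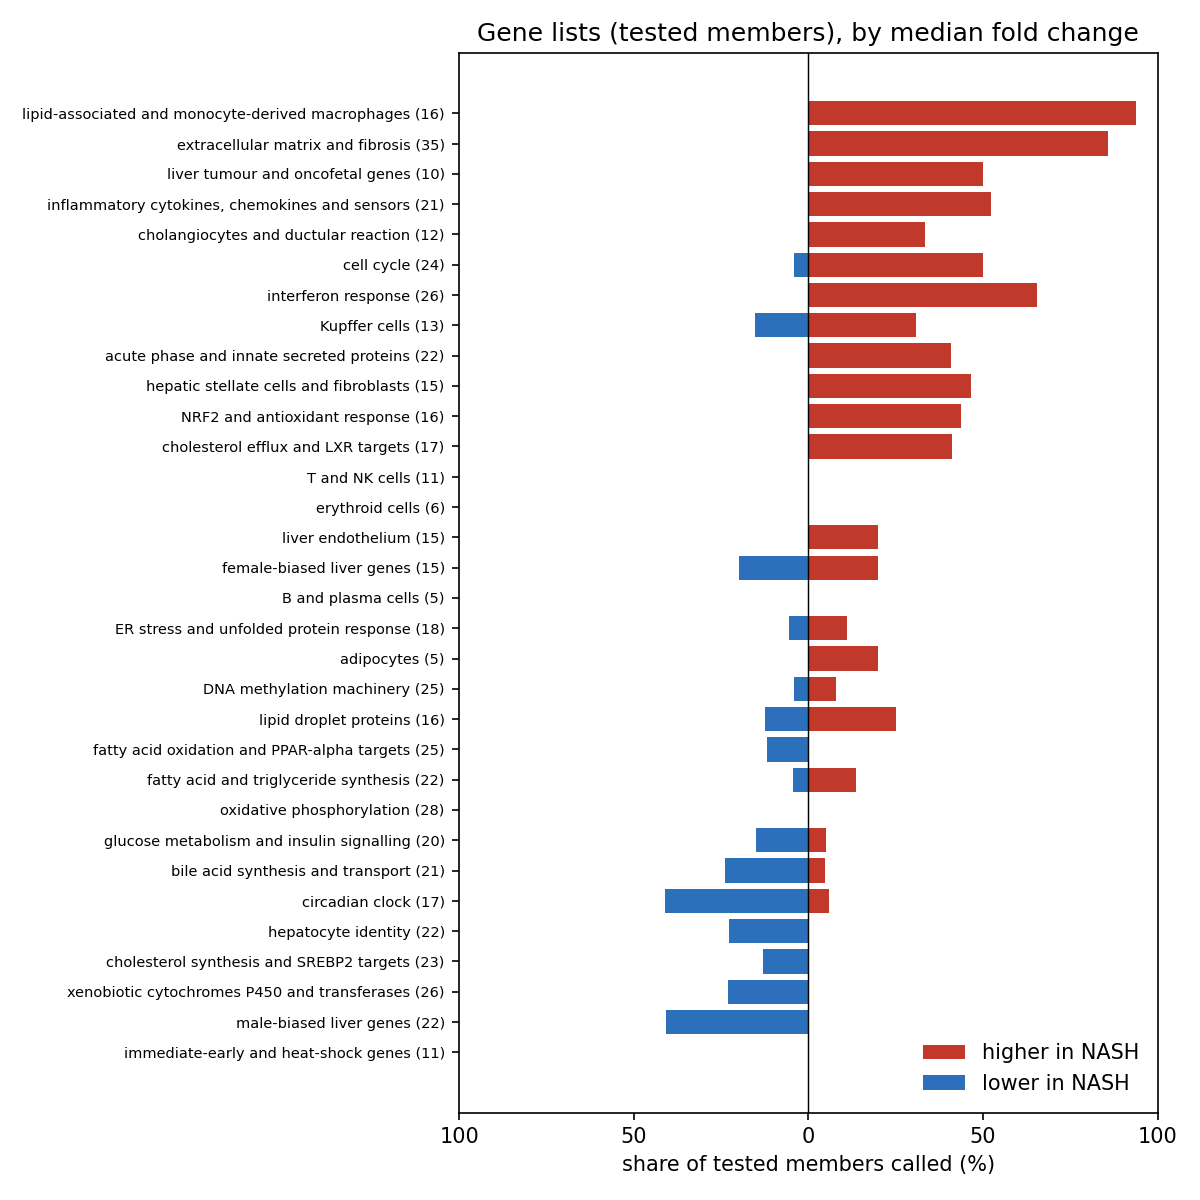
Bars give the percentage of the tested members of each gene list that passed as higher (right) or lower (left) in NASH, with lists ordered by median log2 fold change. The macrophage list has 15 of 16 members higher and the male-biased list 9 of 22 lower.

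Cholesterol efflux genes and targets of the sterol receptor LXR rose in 7 of 17 tested members, and adjusted over the list alone 10 were higher and 1 lower. Lipoprotein lipase Lpl (ENSMUSG00000015568) rose by 3.85 ± 0.56 (adjusted p = 0.00588), the sterol exporters Abcg1 (ENSMUSG00000024030) and Abcg5 by 2.77 ± 0.44 (adjusted p = 0.00749) and 1.26 ± 0.22, and the sterol-esterifying enzyme Soat1 by 2.40 ± 0.45. Without NASH replicate 3 the log2 fold change of Lpl was 3.19. The median of the list was 0.63, or 1.05 with library totals alone (camera adjusted p = 0.00084, adjusted p = 0.251 with an estimated correlation, fry 0.0060). Of the 7 calls, 5 held with each library left out. Cd36 (ENSMUSG00000002944), a fatty acid transporter, rose from 138 ± 43.1 to 526 ± 55.8 CPM (SD, n = 4 each, log2 fold change 1.93 ± 0.24 SE, adjusted p = 0.00368).

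Cholesterol synthesis genes fell in 3 of 23 tested members (9 adjusted over the list alone), and 22 of the 23 had a negative log2 fold change (20 with library totals alone). Hsd17b7 (ENSMUSG00000026675), an enzyme of the pathway, fell by 0.98 ± 0.29 (adjusted p = 0.0436). It did not pass without NASH replicate 4 (0.11), without WT replicates 1 to 4 (0.101, 0.0814, 0.0836 and 0.0973) or without the low-count filter (0.0562). The median was −0.88 (camera adjusted p = 1.1e-06, adjusted p = 0.485 with an estimated correlation, fry 0.0855). Scores were −0.02 and 0.36 in NASH replicates 1 and 2, −1.44 and −1.30 in replicates 3 and 4, and 0.45 to 0.90 in WT.

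Fatty acid and triglyceride synthesis genes did not pass as a list (median −0.35, camera adjusted p = 0.21, fry 0.569), although 3 of its 22 members rose and 1 fell, with the same counts adjusted over the list alone. The lipogenic regulator Srebf1 (ENSMUSG00000020538) rose by 1.19 ± 0.14 (adjusted p = 0.00349), the desaturase Scd2 (ENSMUSG00000025203) by 1.76 ± 0.35 (adjusted p = 0.0131), and the citrate-cleaving enzyme Acly fell by 1.34 ± 0.29. Camera called the list lower than other genes without NASH replicate 2 (adjusted p = 0.0377) and with library totals alone (0.0199), where its median was −0.016 with 11 members positive and 11 negative. Lipid droplet proteins had 4 of 16 members higher and 2 lower, also adjusted over the list alone, and no call as a list (camera adjusted p = 0.891, median −0.13, mean 0.26, and a median of 0.21 with library totals alone). Their scores were 0.29 and 0.61 in NASH replicates 1 and 2, above the WT range of −0.23 to 0.05, and −0.37 and −0.25 in replicates 3 and 4, below it. Fry for movement in either direction, which called 27 of the lists, gave adjusted p = 0.00468 for fatty acid synthesis and 0.000175 for lipid droplets. Plin3 (ENSMUSG00000024197), a droplet coat protein, rose by 1.13 ± 0.12 (adjusted p = 0.00254) and Cidec, which enlarges droplets, by 2.23 ± 0.47, while the lipase inhibitor G0s2 (ENSMUSG00000009633) fell by 1.30 ± 0.23 (adjusted p = 0.00993).

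Genes of fatty acid oxidation and targets of PPAR-alpha fell in 3 of 25 tested members, also adjusted over the list alone (median −0.26, but 0.048 with library totals alone, camera adjusted p = 0.0057, adjusted p = 0.616 with an estimated correlation, fry 0.198). Scores were 0.022 and 0.28 in NASH replicates 1 and 2, within the WT range of −0.049 to 0.41, and −0.55 and −0.49 in replicates 3 and 4. The omega-hydroxylase Cyp4a10 (ENSMUSG00000066072) fell by 1.52 ± 0.37 (adjusted p = 0.0223) and the thioesterase Acot1 (ENSMUSG00000072949) by 1.35 ± 0.35 (adjusted p = 0.0281). Cyp4a10 did not pass without NASH replicate 4 (0.0615) or WT replicates 1, 2 and 3 (0.0677, 0.0544 and 0.0562), nor Acot1 without NASH replicate 3 (0.074) or WT replicates 1, 2 and 3 (0.0823, 0.0521 and 0.0724). Fgf21, a hormone induced by PPAR-alpha, stood at 9.86 ± 9.72 CPM in NASH and 3.56 ± 0.657 in WT and did not pass (log2 fold change 1.48 ± 0.58, adjusted p = 0.103), but did without NASH replicate 1 (0.0215) and with DESeq2 (0.0352).

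Bile acid genes fell in 5 of 21 tested members and 1 rose, also adjusted over the list alone (median −0.50, or −0.19 with library totals alone, camera adjusted p = 2e-04, adjusted p = 0.485 with an estimated correlation, fry 0.0617). The bile-acid-induced repressor Nr0b2 (ENSMUSG00000037583) fell by 1.65 ± 0.34 (adjusted p = 0.0144) and the uptake transporter Slco1a1 by 3.62 ± 0.77, while the exporter Abcc4 (ENSMUSG00000032849) rose by 1.33 ± 0.27 (adjusted p = 0.0139). These 3 calls held with each library left out, with Slco1a1 at −4.42 without NASH replicate 2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, showed no detectable difference at 194 ± 124 CPM in NASH and 184 ± 33.8 in WT (log2 fold change 0.07 ± 0.54, adjusted p = 0.932). Its estimate changed sign without NASH replicate 1 (−0.24), NASH replicate 2 (−0.15) or WT replicate 2 (−0.01).

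Male-biased liver genes fell in 9 of 22 tested members, and adjusted over the list alone 10 were lower and 1 higher. Beside Hsd3b5, the fall was largest in Cspg5 (ENSMUSG00000032482, −5.33 ± 0.85, adjusted p = 0.00747), with 0.0254 ± 0.0507 CPM in NASH against 1.42 ± 0.505 in WT. Its NASH counts were in replicate 3 alone, and without that library the log2 fold change was −8.29, so its size is uncertain. The fall reached the protease inhibitor Serpina1e (−2.67 ± 0.56) and the repressor Bcl6 (−1.73 ± 0.37). The list's median was −1.38 (camera adjusted p = 1.5e-11, adjusted p = 0.312 with an estimated correlation, fry 0.0212). Of the 9 calls, 5 held with each library left out. Scores ran from −2.19 to −0.15 in NASH and from 0.69 to 1.39 in WT. Female-biased genes had 15 tested members, of which 3 rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not pass (median 0.42, camera adjusted p = 0.511). With library totals alone its median was 0.79, while camera placed it below the other genes (0.918). Rtn4 (ENSMUSG00000020458), a membrane-shaping protein of the endoplasmic reticulum, rose by 0.95 ± 0.12 (adjusted p = 0.00379). Another of the 3 that rose, Atp6v0d2, also stands in the macrophage list, and the median without it was 0.37.

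Xenobiotic P450 enzymes and transferases fell in 6 of 26 tested members (13 adjusted over the list alone), and 25 of the 26 had a negative log2 fold change, 22 with library totals alone (median −1.02, camera adjusted p = 3.7e-08, adjusted p = 0.463 with an estimated correlation, fry 0.0524). Cyp2c54 (ENSMUSG00000067225) fell by 2.35 ± 0.51 (adjusted p = 0.0168), but not without NASH replicate 4 (0.0504) or WT replicate 1 (0.0525). Cyp2b10 (ENSMUSG00000030483), a target of the receptor CAR, fell by 3.14 ± 0.75 (adjusted p = 0.0217), but not without NASH replicate 4 (0.0625), WT replicate 1 (0.0617) or WT replicate 3 (0.0552). Without NASH replicate 1 the log2 fold changes of Cyp2c54 and Cyp2b10 were −3.02 and −4.04. None of the 6 calls held in all 8 fits with a library left out. Scores were 0.35 and −0.10 in NASH replicates 1 and 2, −1.74 and −1.29 in replicates 3 and 4, and 0.62 to 0.79 in WT.

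Hepatocyte identity genes fell in 5 of 22 tested members, also adjusted over the list alone, with Foxa3 (ENSMUSG00000040891), a liver transcription factor, at −0.82 ± 0.13 (adjusted p = 0.00735). Foxa3 was the only member whose call held with each library left out, and with library totals alone it did not pass (0.0899). Alb itself did not pass (log2 fold change −0.99 ± 0.41, adjusted p = 0.118) but did with DESeq2 (0.00275) and limma-voom (0.032). The median of the list was −0.72, or −0.42 with library totals alone (camera adjusted p = 8.7e-06, adjusted p = 0.485 with an estimated correlation, fry 0.0612). Glucose and insulin signalling genes fell in 3 of 20 and 1 rose, also adjusted over the list alone. The insulin receptor substrate Irs1 (ENSMUSG00000055980) fell by 1.13 ± 0.14 (adjusted p = 0.00368) and the hexokinase Hk2 (ENSMUSG00000000628) rose by 3.65 ± 0.48 (adjusted p = 0.00426). That list's median was −0.48, or −0.18 with library totals alone (camera adjusted p = 0.019, adjusted p = 0.616 with an estimated correlation, fry 0.157). Its scores were 0.14 and 0.13 in NASH replicates 1 and 2, within the WT range of −0.030 to 0.29, and −0.63 and −0.17 in replicates 3 and 4. Of the 28 oxidative phosphorylation genes, 27 had a negative log2 fold change with a median of −0.39, against 20 and −0.078 with library totals alone (camera adjusted p = 0.00025, adjusted p = 0.616 with an estimated correlation, fry 0.198). Scores were 0.24 and 0.092 in NASH replicates 1 and 2, within the WT range of 0.084 to 0.29, and −0.79 and −0.38 in replicates 3 and 4. EdgeR called 0 of the genes, also adjusted over the list alone, with 4 at an unadjusted p under 0.05. DESeq2 called 1 and limma-voom 4 of them lower. The smallest adjusted p was that of the complex I subunit Ndufv2 (−0.55 ± 0.19, 0.0656), which passed without NASH replicate 1 (0.0173), with DESeq2 (0.0283) and with limma-voom (0.0271).

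Circadian clock genes fell in 7 of 17 tested members and 1 rose (9 and 2 adjusted over the list alone). The repressor Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064) went from 56.4 ± 4.41 CPM in WT to 18.9 ± 4.71 in NASH (SD, n = 4 each, log2 fold change −1.58 ± 0.16 SE, adjusted p = 0.00241). The activators Arntl and Clock fell by 0.91 ± 0.14 (not with library totals alone, adjusted p = 0.0544) and 0.83 ± 0.14, and Nfil3 by 0.76 ± 0.13, while the repressor Nr1d1 rose by 1.10 ± 0.30 (adjusted p = 0.0327, lost without NASH replicates 2 or 4, 0.0709 and 0.0906, or WT replicates 1, 2 or 4, 0.0777, 0.0839 and 0.0850). The median of the list was −0.55, or −0.21 with library totals alone (camera adjusted p = 0.00016, adjusted p = 0.251 with an estimated correlation, fry 0.0107). Of its 8 calls, 5 held with each library left out. The labels used here give no time of day for the sampling.

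DNA methylation machinery did not pass as a list (25 tested, median −0.13, mean 0.05, median 0.24 with library totals alone, camera adjusted p = 0.442, fry 0.488). Of its members, 2 rose and 1 fell, and adjusted over the list alone 4 rose and 3 fell. Uhrf1 (ENSMUSG00000001228), which recruits the maintenance methyltransferase to newly copied DNA, rose by 2.90 ± 0.47 (adjusted p = 0.00749). This call held with each library left out. Dnmt1 (ENSMUSG00000004099), that methyltransferase, rose by 0.74 ± 0.22 (adjusted p = 0.0446) but not without NASH replicate 3 (0.0893) or 4 (0.119) or WT replicate 1 (0.112), 3 (0.114) or 4 (0.111). Zbtb38 (ENSMUSG00000040433), a protein that binds methylated DNA, fell by 0.52 ± 0.13 (adjusted p = 0.0237), but not with library totals alone (0.322), with limma-voom (0.0538), or without NASH replicate 4 (0.0657), WT replicate 2 (0.0638), 3 (0.0512) or 4 (0.0626).

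Markers of other cell types moved to different extents. Kupffer cell markers, of the resident macrophages of the liver, split, with 4 of 13 higher, among them C1qb (2.12 ± 0.41) and Cd5l (2.52 ± 0.51), and 2 lower, among them the scavenger receptor Cd163 (−1.28 ± 0.21). Adjusted over the list alone 7 were higher and 2 lower. The list did not pass (median 1.08, camera adjusted p = 0.21) except without NASH replicate 2 (0.0388) or WT replicate 2 (0.0482). C1qb is expressed by other macrophages too, so its rise need not come from Kupffer cells. Cholangiocyte markers rose in 4 of 12 (6 adjusted over the list alone), with the secreted protein gene Spp1 (ENSMUSG00000029304) at 2.48 ± 0.56 (adjusted p = 0.0186, lost without WT replicate 1, 0.0598, or 4, 0.0562, and at 1.86 without NASH replicate 3). The list's median was 1.57 (camera adjusted p = 0.031, adjusted p = 0.616 with an estimated correlation, fry 0.176). The score was −0.71 in NASH replicate 1 and 0.58 to 1.67 in the other NASH libraries, against −1.02 to −0.29 in WT. Camera did not call the list without NASH replicate 3 (0.121), without WT replicate 4 (0.0646), with library totals alone (0.215) or with the stricter filter (0.184). Endothelial markers rose in 3 of 15, also adjusted over the list alone, led by Cd34 (1.48 ± 0.26), and the list did not pass (median 0.48, or 0.84 with library totals alone, camera adjusted p = 0.24).

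T and NK cell markers (11 tested, median 0.63, or 0.99 with library totals alone, camera adjusted p = 0.342) and B and plasma cell markers (5 tested, median 0.27, or 0.65 with library totals alone, 0.662) had 0 members called by edgeR, also adjusted over the list alone, and 0 at an unadjusted p under 0.05. DESeq2 called 0 of both, and limma-voom 1 T and NK cell marker and 0 B and plasma cell markers. Of the 11, 1 reached a mean of 1 CPM in WT, so changes in these cells were hard to detect at this depth. The 4 tested neutrophil markers had a median of 3.03, with S100a8 at 3.08 ± 1.02 (adjusted p = 0.062), and edgeR called 0 over all genes, with 2 at an unadjusted p under 0.05 and 2 adjusted over the list alone. DESeq2 called 2 of them higher and limma-voom 0. Erythroid genes (6 tested, median 0.57, or 1.00 with library totals alone, camera adjusted p = 0.645) had 0 calls by edgeR, also adjusted over the list alone, with 2 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower and limma-voom 1 lower. Adipocyte genes (5 tested, median −0.10, mean 0.14, camera adjusted p = 0.991, median 0.21 with library totals alone) had 1 call, also adjusted over the list alone, for Fabp4 (2.93 ± 0.40). Of the 11 pancreatic acinar genes 1 was in the table, and it was below the filter. Endoplasmic reticulum stress genes (18 tested, median 0.05, or 0.43 with library totals alone, camera adjusted p = 0.759) had 2 higher and 1 lower, also adjusted over the list alone. Immediate-early and heat-shock genes (11 tested, median −1.70, camera adjusted p = 0.139) had 0 calls by edgeR with 7 at an unadjusted p under 0.05, 1 higher and 5 lower adjusted over the list alone, 1 higher and 2 lower by DESeq2 and 1 higher by limma-voom. That list's score was 2.81 in WT replicate 4, against −1.14 to −0.26 in the other WT libraries and −0.70 to 0.64 in NASH. Camera called the list lower than other genes without WT replicate 3 (adjusted p = 0.0137) and with library totals alone (0.00177), against 0.701 without WT replicate 4.

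**Figure D4:**
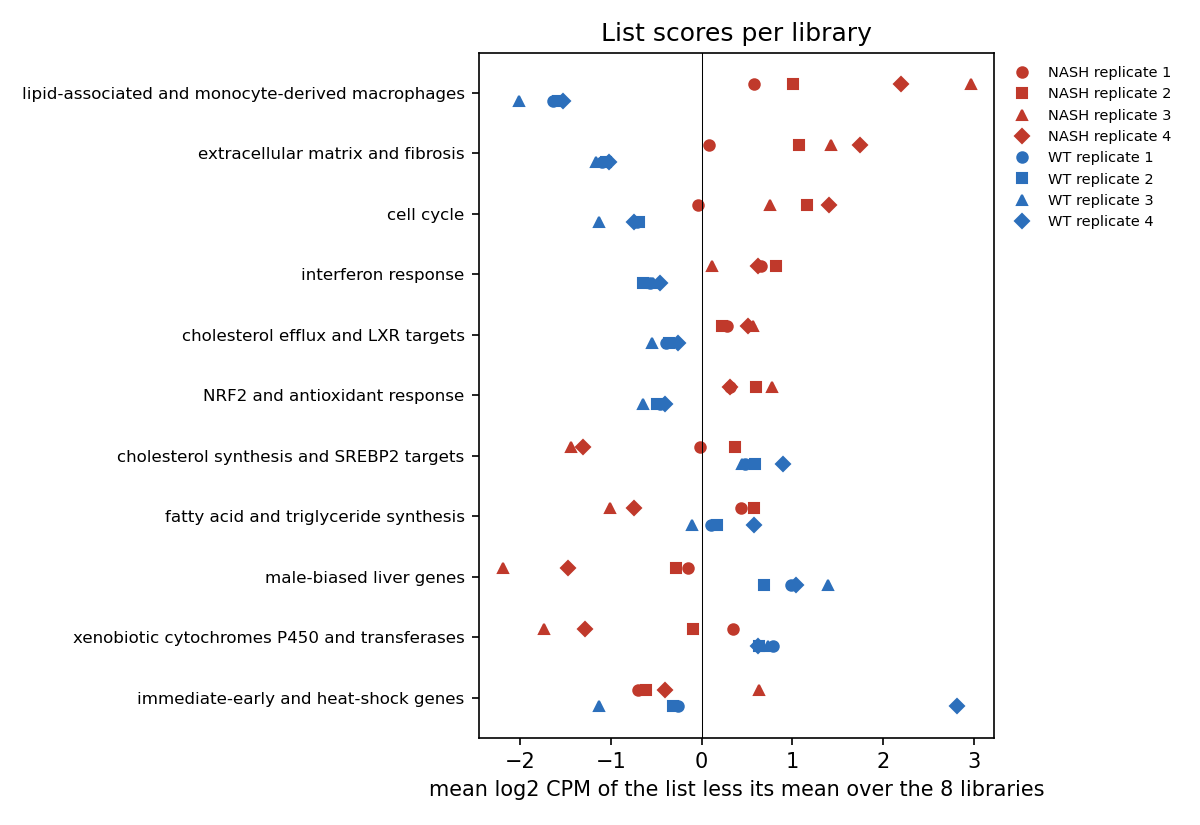
Points give, for selected gene lists, the mean log2 CPM of a list's tested members in each of the 8 libraries less its mean over the libraries, coloured by group with a symbol per replicate. For the macrophage list the NASH libraries lie from 0.58 to 2.96 and the WT libraries from −2.01 to −1.53.

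As a check of the sex given in the labels, the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were read in all groups, at 130 ± 5.28, 24.0 ± 1.27, 79.8 ± 11.6 and 3.75 ± 1.31 CPM in WT and 89.8 ± 14.2, 23.8 ± 2.49, 60.4 ± 14.5 and 3.57 ± 1.22 in NASH. Ddx3y fell by 0.53 ± 0.13 (adjusted p = 0.0225), but not with library totals alone (0.167) or without NASH replicate 4 (0.0632) or WT replicates 1 to 4 (0.066, 0.0594, 0.0537 and 0.0574). Uty (adjusted p = 0.928), Eif2s3y (0.142) and Kdm5d (0.89) did not pass, although Eif2s3y did without NASH replicate 1 (0.032).

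Across the lists, camera called 20 of 32 (11 higher and 9 lower in NASH), fry called 10, and with an estimated correlation 0 were called, with a smallest adjusted p of 0.251 and 6 lists at an unadjusted p under 0.05. Other divisions of the same 8 libraries into 4 and 4 gave up to 26 camera calls and 0 fry calls, so the number of camera calls does not by itself set the NASH and WT division apart.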

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

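The comparison of gene calls and list calls across other splits of the libraries, the dilution test, both cell-type tests and the time-of-day test in this part were chosen only after the result was seen, as were the interferon and macrophage pair, the endothelial comparator and the set of opposite-phase clock genes; the tests of read totals and of scaling were written beforehand. A library far from the other 3 of its group was found in 11 of 198 groups looked at (genes, list scores and library measures), where chance alone gives about 1 in 20, and of the 11, 3 each were in NASH replicate 3, WT replicate 3 and WT replicate 4 and 2 in NASH replicate 1.

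In log2 CPM, NASH replicate 1 stood at 0.57 for Nr0b2 against 2.09 to 2.28 in the other NASH libraries, and at 4.70 for Cry1 against 4.02 to 4.10. NASH replicate 3 stood at 3.97 for Ccl2 against 0.86 to 1.28, at 14.95 for Alb against 16.21 to 16.28, and at −2.55 for Cspg5, of which the other NASH libraries held no counts (−3.85). WT replicate 3 stood at −1.06 for Hk2 against 0.59 to 0.68 in the other WT libraries, at 2.46 for Oasl2 against 2.24 to 2.27, and at −1.14 for the cell cycle score against −0.75 to −0.69. WT replicate 4 stood at 4.74 for Gstm3 against 4.06 to 4.17, at −0.38 for the acute phase score against −0.83 to −0.76, and at −19.1 on the second principal component against 0.152 to 3.44.

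Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as NASH against WT, namely that split itself (2338, highest other 0). Every other split mixes NASH with WT libraries, which widens the spread within its groups and makes calls unlikely. The NASH and WT division thus gave the most gene calls, but this comparison cannot exclude chance. At an unadjusted p under 0.05 the real split gave 4453 genes and the highest other 2634. For the lists called by fry, 1 of the 35 splits gave as many, again the real one (10, highest other 0). At an unadjusted p under 0.05 the numbers were 16 and 8, and the same limit holds. For the lists called by camera with its preset correlation, 15 of the 35 splits gave as many as the real 20, with a highest other of 26, so chance is not excluded for that count.

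The NASH libraries were spread along the first principal component, with replicates 3 and 4 far from WT and replicate 1 nearest. After thinning all libraries to the smallest total, the NASH range was still 49.8 against 9.23 in WT, and with library totals alone it was 57.5 against 10.2, which argues against read totals and scaling as the source. Admixture of control RNA would shrink all changes in a library alike. In NASH replicate 1 the median share of the mean change of the other NASH libraries was 1.14 for interferon genes and 0.244 for macrophage genes. The difference was 0.90 (95% bootstrap interval over genes 0.681 to 1.23). In NASH replicates 2, 3 and 4 the shares were 1.41, 0.313 and 0.939 for interferon and 0.364, 3.17 and 1.27 for macrophage genes. Replicate 3, low on interferon and high on macrophage genes, is part of the mean that replicate 1 was set against. Unequal shares in replicate 1 therefore cannot decide on admixture, which stays open. A difference in disease severity or in the piece of liver sampled may also account for the spread and stays open, as untested.

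In NASH 15 of 16 macrophage and 30 of 35 matrix genes were higher and 5 of 22 hepatocyte identity genes lower, and none of these lists passed camera with an estimated correlation (adjusted p = 0.251, 0.251 and 0.485). A lower share of hepatocytes alone would raise the markers of all other cell types alike. The median log2 fold change of the macrophage list instead exceeded that of the endothelial list by 2.93 (95% bootstrap interval over genes 1.84 to 4.27). The genes of each list move together (estimated correlation 0.888 for macrophage and 0.456 for endothelial genes), so this interval is likely too narrow. The comparison also takes expression per endothelial cell as unchanged, which bulk RNA does not show. Stellate, cholangiocyte, and T and NK cell medians were 0.93, 1.57 and 0.63, but the 4 tested neutrophil markers had a median of 3.03. The medians of the macrophage and Kupffer lists differed by 2.33 (1.04 to 4.51). More resident Kupffer cells would raise both lists alike only if those cells carry the genes of both. Bulk RNA does not show this, and Trem2 and Cx3cr1 of the macrophage list stood at 0.173 and 0.547 CPM in WT. The comparison therefore does not decide whether Kupffer cells became more numerous. Of the 16 tested macrophage markers 14 reach a mean of 1 CPM in WT liver and 2 stand in another list. The lysozyme gene Lyz2 and Gpnmb stood at 401 and 259 CPM in NASH against 74.0 and 2.21 in WT. Lyz2 lost its edgeR call without WT replicate 1 (adjusted p = 0.0617), 3 (0.0546) or 4 (0.0562). Its log2 fold change went from 2.44 to 1.84 without NASH replicate 3. A larger number of recruited or resident macrophages, or more expression per cell, may account for the rise, and these were not separated.

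Of 17 clock genes 7 were lower and 1 higher in NASH, and the list did not pass camera with an estimated correlation (adjusted p = 0.251). If the groups had been sampled at different times of day, genes that peak opposite to Arntl and Clock could have moved the other way. Their median log2 fold change was −0.12 (95% bootstrap interval −1.06 to 0.96), with 3 of 9 positive and 6 negative. These 9 genes do not all peak at the same hour, so a time difference need not move them alike. A difference in sampling time and a change in the clock genes themselves therefore cannot be told apart from these values. The labels used here give no time. A difference in diet, if the groups are read that way, stays open as untested.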

How the results depend on the processing

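The list medians with library totals alone were added only after the result was seen, and the other tests in this part were chosen beforehand. Of the 51 named genes that passed, 48 did so in every scaling, 47 with both other tools and 37 with each library left out, and none changed direction. With the replicate number as a block 38 of them passed, and 37 passed the test against a fold change of 1.5. Those lost with the block included G0s2 (edgeR adjusted p = 0.0574) and Abcc4 (0.0672). Of the 20 lists called by camera, 19 were called in every scaling and 19 with each library left out. DESeq2 called 3527 genes, 1361 of them lower, limma-voom called 1222 lower, library totals alone gave 3071 higher and 220 lower, and the test against a fold change of 1.5 called 560 (514 higher, 46 lower). With single libraries left out the calls ran from 821 to 3742, those higher from 636 to 2238 and those lower from 185 to 1504; such fits have fewer samples. By camera with an estimated correlation 0 lists passed (6 at an unadjusted p under 0.05), and by fry 10. The first component held 62.8% of the variance with all tested genes. The depth and 4 libraries per group limit what can be seen of changes under 2-fold and of genes near the filter.

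Camera's sign, which sets a list against all other genes, turned only for lists that it did not call. With library totals alone it turned for the female-biased, ER stress and erythroid lists (adjusted p = 0.918 each) and the B and plasma cell list (0.913), although their medians were higher there (0.79, 0.43, 1.00 and 0.65). The median of the fatty acid oxidation list, which camera called lower, turned from −0.26 to 0.048 there. Of the genes, Kdm5d (log2 fold change 0.24) and Uty (0.33) turned, and neither had passed. The cause of these and the following turns was not tested. The lipid droplet list turned with fry (0.847). With some single libraries left out the lipid droplet, ER stress and adipocyte lists turned too, and their adjusted p over all such fits ran from 0.381 to 0.915, 0.381 to 0.963 and 0.305 to 0.975. The adipocyte list also turned with fry (0.763), DESeq2-type size factors (0.998) and no filter (0.776). Uty was at 0.039 with limma-voom and 0.0081 with the stricter filter. With single libraries left out, Cyp7a1 ran from −0.24 to 0.42, Kdm5d from −0.31 to 0.17 and Uty from −0.082 to 0.016.

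With the replicate number as a block, edgeR called 618 genes (467 higher, 151 lower), of which 611 were shared with the fit without it, the lipid droplet list turned with camera (0.709) and with fry (0.597), Cyp7a1 was at −0.21, and fry called 0 lists. The numbers share no stated origin, and deviations of same-numbered libraries correlated at 0.034, −0.139, −0.144 and −0.016 across genes, below the highest with another number (0.101, 0.113, 0.240 and 0.120), so the numbers were not read as pairing. A restriction to protein-coding genes was not run because all genes in the table are of that kind, and the alternatives for normalized values did not apply to counts.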

Other observations

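The test of the sex-biased lists, the choice of the pathways and of the immediate-early genes named here, and the count of camera calls over splits came only after the values were seen, and the pathway lists themselves were added after the data had been seen; the test of other splits for the pathways called by fry was written before its result. Of the genes named here, 4 serve antigen presentation on MHC class II, which was not tested as a list. Ciita, the master regulator of the class II genes, rose by 2.94 ± 0.29 on the log2 scale (edgeR adjusted p = 0.00199), H2-Aa by 2.38 ± 0.22, H2-Ab1 by 2.22 ± 0.22 and the invariant chain gene Cd74 by 1.94 ± 0.25. Of 54 tested genes of the KEGG pathway of antigen processing and presentation, 18 were higher and 2 lower (median 0.24, 34 positive, fry adjusted p = 0.00636, camera adjusted p = 0.621 with an estimated correlation). Lysosomal genes were higher in 35 of 111 and lower in 4 (fry adjusted p = 0.0199, camera adjusted p = 0.621 with an estimated correlation), with the cathepsin Ctss at 2.64 ± 0.44. Genes of leukocyte passage through the endothelium were higher in 35 of 88 and lower in 2 (fry adjusted p = 0.0398, camera adjusted p = 0.621 with an estimated correlation), with the chemokine receptor Cxcr4 at 2.72 ± 0.32 and the integrin Itga4 at 2.45 ± 0.35. Camera called 117 of the 272 pathways with its preset correlation, and since 8 of the 35 splits of the libraries gave as many (highest other 147), chance is not excluded for that count. It called 0 with an estimated correlation, with a smallest adjusted p of 0.621 and 14 at an unadjusted p under 0.05.

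Sphingolipid genes rose in 8 of 36 tested members (fry adjusted p = 0.0199, camera adjusted p = 0.621 with an estimated correlation), with Sptlc2, a subunit of the enzyme of the first step, at 1.40 ± 0.25. Ether lipid genes rose in 8 of 26 and fell in 1 (fry adjusted p = 0.00756, camera adjusted p = 0.621 with an estimated correlation), with the phospholipase Pla2g7 at 2.80 ± 0.41 and the acyltransferase Lpcat1 at 1.37 ± 0.22. Glycerophospholipid genes, with 12 of 63 higher and 4 lower, did not pass (fry adjusted p = 0.23). Of 74 genes of mRNA surveillance 10 were lower and 1 higher (fry adjusted p = 0.00962, camera adjusted p = 0.621 with an estimated correlation). Fip1l1, a factor of 3-prime end processing, fell by 0.62 ± 0.10 and Upf3b, a factor of nonsense-mediated decay, by 0.46 ± 0.09, but neither passed with library totals alone (adjusted p = 0.163 for Fip1l1 and 0.6 for Upf3b). Fry called 101 of the 272 pathways. Of the 35 splits of the libraries, 1 gave as many, namely the real one, with a highest other of 0. The other splits mix NASH with WT libraries, so this does not exclude chance for that count. At an unadjusted p under 0.05 the real split gave 158 and the highest other 102.

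Of 22 male-biased genes 9 were lower in NASH, and the list did not pass camera with an estimated correlation (adjusted p = 0.312). A hypothesis is that the livers switched to the female pattern, with female-biased genes higher by as much as male-biased genes were lower. The medians of the lists would then sum to about 0. Their sum was −0.96 (95% bootstrap interval −1.96 to −0.32), with −1.38 for the male-biased and 0.42 for the female-biased list, but with library totals alone it was −0.33 (−1.38 to 0.32), with −1.12 and 0.79, and −1.02 (−2.09 to −0.42) with TMM but without Atp6v0d2, which the macrophage list shares. A switch of equal size and a loss of male-biased expression by another route cannot be told apart, because the sum depends on the scaling.

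Immediate-early genes were high in WT replicate 4. Fos, a transcription factor induced within minutes of a stimulus, was at 576 CPM there and at 1.92 to 8.38 CPM in the other WT libraries, and Egr1 was at 958 against 14 to 52.0 CPM. The score of the immediate-early and heat-shock list was 2.81 in that library and −1.14 to −0.26 in the other WT libraries.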
